A study of Homo sapiens with 16 samples.

How the data were processed

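RNA was sequenced from MDA-MB-231 and SKBR3 cells, controls or given 500 nM MitoQ for 48 h, in 16 libraries. The values used were estimated counts per gene, whole numbers as deposited by the authors, who named Salmon, edgeR and the build GRCh38 per the submitters' processing notes. The versions, the annotation release, the step from transcripts to genes and any rounding were not given in the sources used here. The values were checked to be whole numbers of at least 0 with different totals per library. The table held 35106 gene rows with Ensembl IDs and symbols, 8866 of them with no count in any library. Of these rows 35003 matched GENCODE release 29 by ID and 103 did not; type, position and chromosome come from that release on GRCh38. There were 19788 protein-coding and 14860 pseudogene rows, and 17 long non-coding or antisense rows. For a symbol on more than 1 ID, which 16 symbols had, the ID with the higher total was used.

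Groups were line and treatment. The column names of the SKBR3 libraries carry the number of the other line, but their marker genes were those of SKBR3: ERBB2 lay at 5282 CPM in the SKBR3 controls and 53 CPM in the MDA-MB-231 controls. The origin of the replicates and the treatment of controls were not given in the sources used here. The lines were at passage 25 (MDA-MB-231) and 10 (SKBR3), so line and passage cannot be told apart. The total per library ranged from 14723152 to 29294865, and a count of 0 allows up to 3 counts of that total, 0.1 to 0.2 CPM. Intervals and floors cover counting error only.

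Genes were kept with filterByExpr, scaled with TMM and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust spread, two-sided F test), with Benjamini-Hochberg adjustment and a threshold of 0.05. An adjusted p of a gene comes from that test unless another tool is named beside it. The SE is the absolute log2 fold change over the square root of F. Treatment was tested within each line. The difference of the effects was the interaction term over all 16 libraries, and the control lines were compared over the 8 controls. No replicate block was used. CPM values are normalised within each comparison and differ slightly between them.

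The 43 gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 with a preset correlation of 0.01, where at least 5 members were tested, with adjustment over the lists. Metallothioneins had fewer tested members in SKBR3 and were not tested there. Camera was run again with an estimated correlation between genes, and fry was run beside it. Fry tests whether the genes of a list move on balance 1 way and does not compare the list with other genes. Counts within a list were also adjusted over the list alone.

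Genes named in the text follow a rule written before the data were examined. For each treatment comparison it takes the 10 largest rises and 10 largest falls among called protein-coding genes with a mean of at least 5 CPM and no overlap between groups. It adds the 3 members with the smallest p of each called list, 6 genes per direction for the interaction, the 4 largest folds in each of the line marker lists, and a panel of 20 genes. Which of the list members serve as examples was chosen after their values were seen, as were MT-ND1, MT-ND2, and the scans for genes near 0. Of each named gene the share of 31-base stretches found in annotated transcripts of other genes was computed. Of the members of the lists, 2 genes are not reported here.

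Alternatives fixed before the data were examined were other size factors, DESeq2 1.42.0, limma voom with quality weights, no filter, a filter at 1 CPM, a threshold of 0.01, a test against a 1.2-fold change, mitochondrial genes left out, a replicate block, a single fit over all libraries, and each library left out in turn. Plain library totals, MDA-MB-231 thinned to the size of SKBR3, the interaction among genes tested within both lines, and for the lists mitochondrial genes left out, were added after the data were seen. The comparisons were repeated on at most 100 other splits of the libraries.

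The tests were tested on simulated data with 200 changed genes in each of 3 simulations per comparison; this was first 1 simulation and was then widened. Changes of 1.25-fold, 1.5-fold and 2-fold were recovered in 51%, 77.3% and 94.8% of cases for MDA-MB-231, with 6.61% of calls false. For SKBR3 they were recovered in 45.2%, 70.5% and 85.3%, with 11.5% false. For the interaction the shares were 16.2%, 58.9% and 71%, with 4.68% false, and for the control lines 57.6%, 72.6% and 82%, with 5.88% false. The shares of false calls hold for 200 changed genes and do not carry over to the real comparisons, where many more genes were called. For the interaction each simulated gene had the same base level in both lines. In the data 14177 of 16398 genes differed between the control lines, so the interaction shares do not describe genes with unequal levels. In each comparison 3 of 3 changed lists and 0 of 120 unchanged lists were called by camera with the preset correlation. The genes were simulated independently of each other, so these counts do not check whether the preset correlation is high enough for the real lists.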

Results

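Gene expression was measured by RNA sequencing in 16 libraries from 2 human breast cancer cell lines. MDA-MB-231 is a triple-negative line with mesenchymal traits, and SKBR3 is a line with an amplified ERBB2 (HER2) gene. Cells were controls or received 500 nM MitoQ for 48 h. MitoQ is a ubiquinone joined to a lipophilic triphenylphosphonium cation, which makes it accumulate in mitochondria. There were 5 control and 5 MitoQ libraries of MDA-MB-231 at passage 25, and 3 control and 3 MitoQ libraries of SKBR3 at passage 10. What the control cells received was not given in the sources used here. The total of estimated counts per library was 23612986 to 29294865 in MDA-MB-231 controls, 19844695 to 25904852 in MDA-MB-231 MitoQ libraries, 14723152 to 27841144 in SKBR3 controls and 19157771 to 27739692 in SKBR3 MitoQ libraries. A count of 0 allowed a level of up to 0.1 CPM in the deepest library and 0.2 CPM in the shallowest, for counting error only. Levels below are normalised CPM, counts scaled to the library size, as mean ± SD. Changes are log2 fold changes ± SE from edgeR, with n = 5 and 5 in MDA-MB-231 and n = 3 and 3 in SKBR3.

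The first comparison asked which genes changed in MDA-MB-231 cells given MitoQ, as part of a search for markers of response. Genes of the integrated stress response, the ATF4 programme set off by amino acid shortage and by mitochondrial stress, rose together. Each of its 24 tested members was higher, 24 adjusted over the list alone, with a median log2 fold change of 1.66, a 3.17-fold rise. Genes of mitosis fell in 30 of 30 tested members, 30 adjusted over the list alone, with a median of -1.02. The mRNAs encoded in mitochondrial DNA, histone mRNAs and enzymes of cholesterol synthesis fell as well, the last not past the test with an estimated correlation between genes (adjusted p = 0.168). Of 15304 genes tested, 8805 changed at an adjusted p under 0.05, 4574 higher and 4231 lower. The change was at least 2-fold in 708 of the higher and 320 of the lower genes. With plain library totals in place of scaling factors 60.5% of the called genes were higher, against 51.9% with scaling factors.

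The largest rise was that of KLHDC7B (ENSG00000130487, chromosome 22, 50545891 to 50551023), from 0.0642 ± 0.0236 to 10.7 ± 0.638 CPM. It had 8 counts over the 5 control libraries and 1274 over the 5 MitoQ libraries, a ratio of 169 with a 95% counting interval of 85.4 to 392. INHBE (ENSG00000139269, chromosome 12, 57452323 to 57459280), an inhibin subunit, went from 0.365 ± 0.0850 to 18.9 ± 1.61 CPM. PAPPA2 (ENSG00000116183, chromosome 1, 176463171 to 176845605), a protease of IGF-binding proteins, went from 4.45 ± 0.420 to 200 ± 14.6 CPM, a log2 fold change of 5.49 ± 0.074 (adjusted p = 3.91e-20). GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176), a cytokine secreted under cell stress, rose 14.6-fold (log2 3.86 ± 0.12, adjusted p = 8.43e-14). The other genes among the 10 largest rises were S100P, ST6GALNAC3, PIP5KL1, SLC16A1, ANKFN1 and SEL1L3, with log2 fold changes between 5.67 and 3.59. S100P was near the floor in the controls, so the size of its rise is not interpretable. Among the 10 largest falls 7 were histone genes, from HIST1H2AA (-3.58 ± 0.096) and HIST1H2BA (-3.08 ± 0.088) to HIST1H2BM, HIST1H3J, HIST1H2AB, HIST1H2BB and HIST2H3D (-2.38 ± 0.12). The others were MT-ND6, MT-CO3 and the helicase gene PIF1 (-2.57 ± 0.081). Of the 31-base stretches of HIST2H3D, 86.4% occur in transcripts of other genes, and of those of HIST1H3J 42.4%, so their counts are less certain than those of HIST1H2AA.

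**Figure D1:**
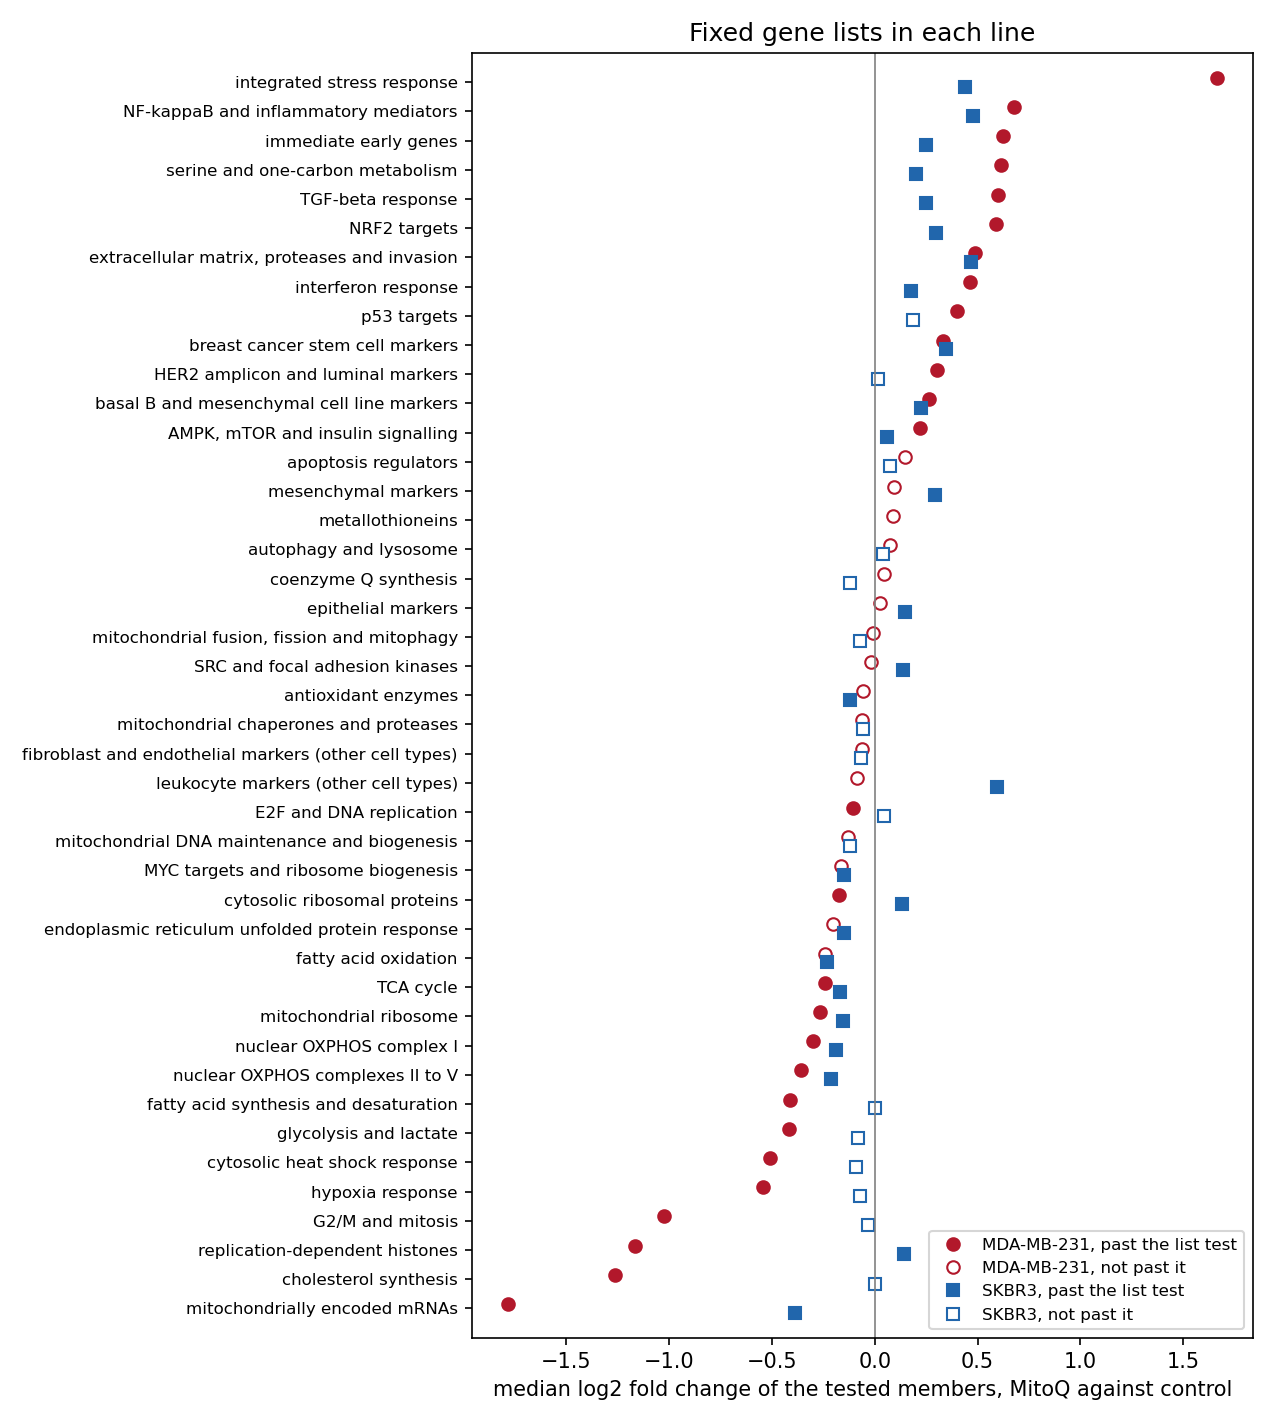
Median log2 fold change of the tested members of each fixed gene list (horizontal axis), MitoQ against control, for MDA-MB-231 (circles, n = 5 and 5) and SKBR3 (squares, n = 3 and 3); filled symbols passed the list test with the preset correlation. In MDA-MB-231 the integrated stress response lies at 1.66 and the mitochondrially encoded mRNAs at -1.78, and the SKBR3 medians of these lists are 0.44 and -0.39.

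Stress-response and amino acid genes rose in MDA-MB-231. Asparagine synthetase (ASNS) went from 58.7 ± 3.47 to 451 ± 11.5 CPM, a 7.68-fold rise, with 42.5% of its 31-base stretches in other transcripts. CTH, which makes cysteine from cystathionine, rose 8.17-fold, NUPR1, a stress-induced transcription regulator, 9.77-fold, and TRIB3, a pseudokinase induced by ATF4, 8.97-fold. CHAC1, which degrades glutathione, rose 7.90-fold, and the mRNA of ATF4 itself 1.78-fold; DDIT3 (CHOP) went from 9.70 to 29.1 CPM. The list held with an estimated correlation between genes (adjusted p = 0.00132). In the serine and one-carbon list 9 of 14 members rose and 5 fell, the same counts adjusted over the list alone (9 and 5), and it also held (adjusted p = 0.0126 with an estimated correlation). PSAT1 rose 4.22-fold, MTHFD2 3.34-fold and PHGDH, the first enzyme of serine synthesis, 2.94-fold. In the p53 target list 13 of 22 members rose and 2 fell, 13 and 3 adjusted over the list alone (adjusted p = 0.00757 with an estimated correlation). SESN2 (7.38-fold) and GDF15 stand in both this list and a stress or nutrient list, and CDKN1A, which codes for the cell cycle inhibitor p21, rose from 48.5 ± 3.54 to 161 ± 24.6 CPM.

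Genes of cell division fell in MDA-MB-231. KIF20A, a mitotic kinesin, went from 158 ± 6.95 to 35.4 ± 1.61 CPM, AURKA from 204 ± 5.84 to 61.5 ± 1.35 CPM and CCNB1 (cyclin B1) from 272 ± 13.5 to 87.1 ± 2.65 CPM. MKI67, a proliferation marker, fell 2.12-fold. The G2/M list held with an estimated correlation (adjusted p = 0.00132). The replication-dependent histone list fell in 12 of 13 members, 12 adjusted over the list alone, with a median of -1.17 (adjusted p = 0.0428 with an estimated correlation); HIST1H4C went from 686 ± 56.8 to 227 ± 14.7 CPM. That list also held H1F0, a histone gene expressed outside replication. Genes of DNA replication under E2F moved little: 14 of 30 fell and 2 rose, 14 and 2 adjusted over the list alone, with a median of -0.11 and GINS2 at -0.60 ± 0.058. The E2F list was lost with an estimated correlation (adjusted p = 0.593).

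In MDA-MB-231 the share of counts on the 13 mitochondrially encoded mRNAs went from 3.31% ± 0.233 to 1.11% ± 0.134. Of these mRNAs 12 fell, 12 adjusted over the list alone, with a median of -1.78, and the list held with an estimated correlation (adjusted p = 0.0428). MT-CO3 went from 5472 ± 389 to 754 ± 91.5 CPM, MT-CO1 from 8092 ± 504 to 1826 ± 133 CPM and MT-CYB from 1896 ± 88.3 to 544 ± 53.5 CPM. The steepest fall was that of MT-ND6 (-2.96 ± 0.18). MT-ND1 fell least among the called genes (-0.40 ± 0.11), and MT-ND2 did not pass the test (-0.19 ± 0.10, adjusted p = 0.146); both were singled out after their values were seen. Part of the sequence of these genes recurs in nuclear copies: 66.7% of the 31-base stretches of MT-CO1 and 45% of those of MT-CO3 occur in other annotated transcripts. For MT-ND1 and MT-ND2 this share was not computed.

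**Figure D2:**
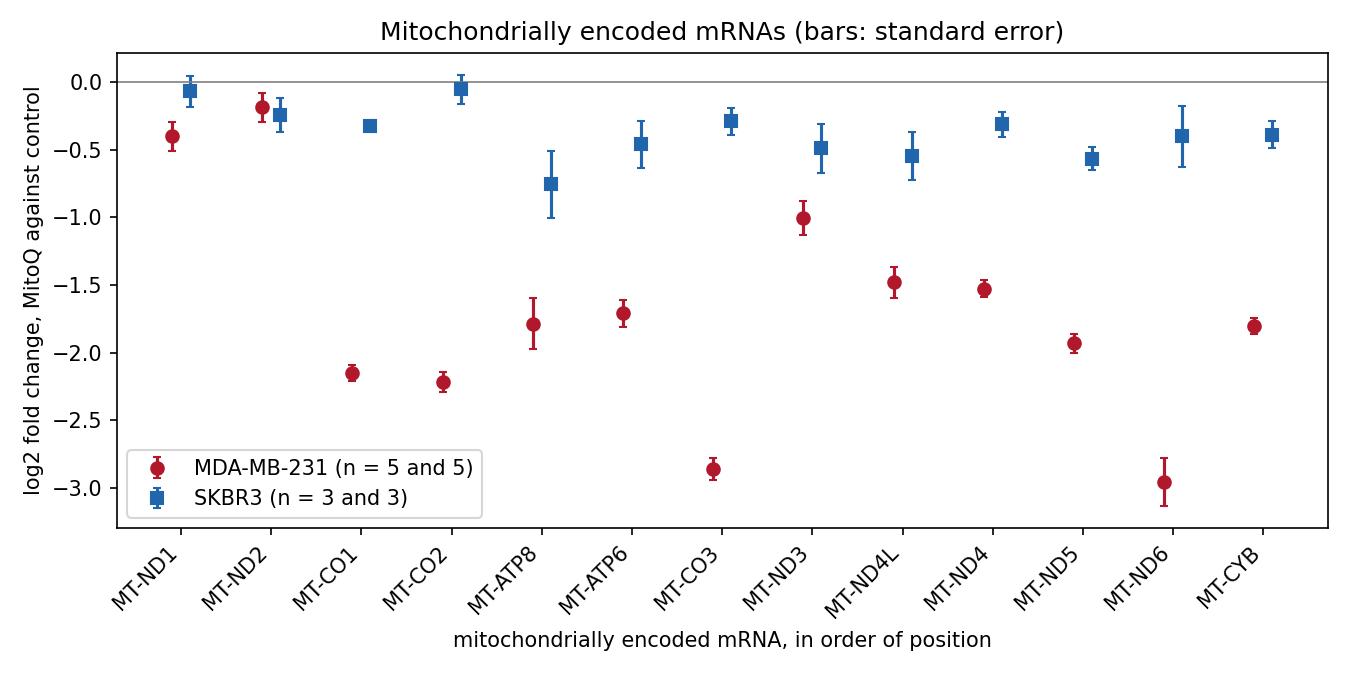
Log2 fold change of each mitochondrially encoded mRNA (vertical axis; bars, SE) in order of position on mitochondrial DNA, for MDA-MB-231 (circles, n = 5 and 5) and SKBR3 (squares, n = 3 and 3). In MDA-MB-231 the values run from -2.96 for MT-ND6 to -0.19 for MT-ND2.

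Nuclear genes of oxidative phosphorylation fell by less. In complexes II to V 32 of 39 members fell, 32 adjusted over the list alone, with a median of -0.36, and in complex I 24 of 37 fell and 2 rose, 24 and 2 adjusted over the list alone, with a median of -0.30. These lists were lost with an estimated correlation (adjusted p = 0.211 and adjusted p = 0.387). ATP5MC1 and ATP5MC3, subunits of the ATP synthase ring, had values of -1.09 ± 0.063 and -0.86 ± 0.041, NDUFB3 -0.71 ± 0.062 and NDUFAB1 -0.51 ± 0.050. The mitochondrial ribosome list fell in 48 of 73 members and rose in 3, 50 and 5 adjusted over the list alone, with a median of -0.26 (MRPL35, -0.55 ± 0.045; adjusted p = 0.319 with an estimated correlation). The TCA cycle list fell in 13 of 21 and rose in 1, 13 and 1 adjusted over the list alone (CS, citrate synthase, -0.48 ± 0.042; adjusted p = 0.294 with an estimated correlation). In glycolysis and lactate metabolism 19 of 24 members fell and 3 rose, 19 and 3 adjusted over the list alone (adjusted p = 0.286 with an estimated correlation). LDHA (lactate dehydrogenase A) fell 2.31-fold and PDK1 2.58-fold, while the lactate transporter gene SLC16A1 rose from 1.13 ± 0.321 to 14.7 ± 2.37 CPM. HK2 was lower by little (-0.15 ± 0.053, adjusted p = 0.0221), and this call was lost without MDA-MB-231 control 2 (adjusted p = 0.0728), without control 3 (adjusted p = 0.0610), without MitoQ 3 (adjusted p = 0.0696) and with plain library totals (adjusted p = 0.152).

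Cholesterol synthesis fell in 22 of 25 members, 22 adjusted over the list alone, with a median of -1.26; this call was lost with an estimated correlation (adjusted p = 0.168). HMGCS1, an early enzyme of the pathway, went from 206 ± 5.59 to 57.7 ± 17.0 CPM, ACAT2 fell 2.59-fold and MVK 3.15-fold, and CYP51A1 fell 2.47-fold with 80.0% of its 31-base stretches in other transcripts. Fatty acid synthesis fell in 11 of 16 and rose in 4, 11 and 4 adjusted over the list alone (ELOVL6, -0.75 ± 0.049; adjusted p = 0.301 with an estimated correlation). The NRF2 targets, genes of the antioxidant response, rose in 17 of 22 and fell in 1, 17 and 1 adjusted over the list alone, and held (adjusted p = 0.0428 with an estimated correlation). The ferritin genes FTL and FTH1 rose 3.08-fold and 2.40-fold, NQO1 2.86-fold, TXNRD1 1.56-fold and HMOX1 1.56-fold. SOD2 (-0.058 ± 0.058, adjusted p = 0.413) did not pass the test.

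Matrix, TGF-beta and inflammatory genes rose in MDA-MB-231. In the matrix and invasion list 24 of 30 rose and 2 fell, 25 and 3 adjusted over the list alone (adjusted p = 0.168 with an estimated correlation). COL6A3 (collagen VI) went from 27.9 ± 1.22 to 254 ± 26.6 CPM and the integrin gene ITGA3 rose 2.05-fold. The TGF-beta response rose in 15 of 20 and fell in 4, 15 and 4 adjusted over the list alone (adjusted p = 0.0365 with an estimated correlation), with ID1 2.78-fold higher. NF-kappaB targets rose in 17 of 22 and fell in 1, 17 and 1 adjusted over the list alone (adjusted p = 0.0134 with an estimated correlation), with IL1B 6.54-fold, TNFAIP3 2.76-fold and CXCL8 2.33-fold higher. Immediate early genes rose in 16 of 19, 17 adjusted over the list alone (DUSP1, 2.33-fold; adjusted p = 0.113 with an estimated correlation). The interferon list rose in 22 of 29 and fell in 1, 22 and 1 adjusted over the list alone (adjusted p = 0.385 with an estimated correlation); IFIT2 rose 2.52-fold and STAT2 1.78-fold, while DDX58, the RNA sensor gene, fell 2.40-fold. The signalling list of AMPK, mTOR and insulin rose in 13 of 22 and fell in 3, 13 and 3 adjusted over the list alone (adjusted p = 0.0428 with an estimated correlation), among them SESN2 (7.38-fold), TXNIP, a regulator of glucose uptake, which went from 90.8 ± 3.23 to 478 ± 6.36 CPM, and DDIT4 (2.85-fold).

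The cytosolic heat shock list fell in 10 of 10 members, 10 adjusted over the list alone (adjusted p = 0.0428 with an estimated correlation), with HSPA8 1.76-fold and HSPH1 1.76-fold lower. The hypoxia list fell in 13 of 20 and rose in 5, 14 and 5 adjusted over the list alone (adjusted p = 0.10 with an estimated correlation); BNIP3 fell 2.05-fold, while VEGFA rose 2.08-fold. Cytosolic ribosomal protein genes fell in 33 of 62 and rose in 2, 33 and 2 adjusted over the list alone (RPS7, -0.57 ± 0.057; adjusted p = 0.686 with an estimated correlation). The basal B marker list rose in 12 of 20 and fell in 3, 12 and 4 adjusted over the list alone (EGFR, 1.63-fold; adjusted p = 0.198 with an estimated correlation). The stem cell marker list rose in 8 of 15 and fell in 3, 8 and 3 adjusted over the list alone (KLF4, 2.70-fold; adjusted p = 0.168 with an estimated correlation). The luminal marker list rose in 12 of 20, 12 adjusted over the list alone (XBP1, 2.59-fold; adjusted p = 0.319 with an estimated correlation). ERBB2 (0.0050 ± 0.058, adjusted p = 0.951) and PPARGC1A (-0.037 ± 0.13, adjusted p = 0.833) did not pass the test. VIM (0.038 ± 0.053, adjusted p = 0.567) and TFAM (-0.15 ± 0.070, adjusted p = 0.0828) did not pass it either, but did without MDA-MB-231 MitoQ 2 (adjusted p = 0.0332 and adjusted p = 0.00233), TFAM also in limma voom with quality weights (adjusted p = 0.00171) and in a single fit over all libraries (adjusted p = 0.0180). The markers of leukocytes (median -0.087) and of fibroblasts and endothelium (median -0.062) did not pass the list test.

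In total 27 of 43 lists passed the test in MDA-MB-231, 13 up and 14 down, and 11 of them with an estimated correlation. The lists that did not pass covered lysosome and autophagy (median 0.072), fatty acid oxidation (-0.24), antioxidant enzymes (-0.058), mesenchymal markers (0.093), MYC targets (-0.17), apoptosis (0.15), mitochondrial chaperones (-0.061), the endoplasmic reticulum response (-0.20), SRC kinases (-0.021), mitochondrial DNA maintenance (-0.13), fusion and fission (-0.010), metallothioneins (0.087), epithelial markers (0.027) and coenzyme Q synthesis (0.043). Other splits of the same 10 libraries called up to 28 lists, so the number of called lists did not exceed that of other splits. The split with 28 differed from the real one by 2 libraries. It kept part of the treatment contrast, so it does not stand for chance alone. For 25 of the 27 called lists no other of the 100 splits drawn had a median as large. Every other split mixes treated and control libraries, which dilutes a difference between them, so a smaller median was likely in advance. The median and the test, or the mean, differed in sign for SRC kinases, fusion and fission, leukocyte markers, coenzyme Q synthesis and fibroblast markers, and these lists did not pass. In the test against a change of 1.2-fold, 4400 genes passed in place of 8805.

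**Figure D3:**
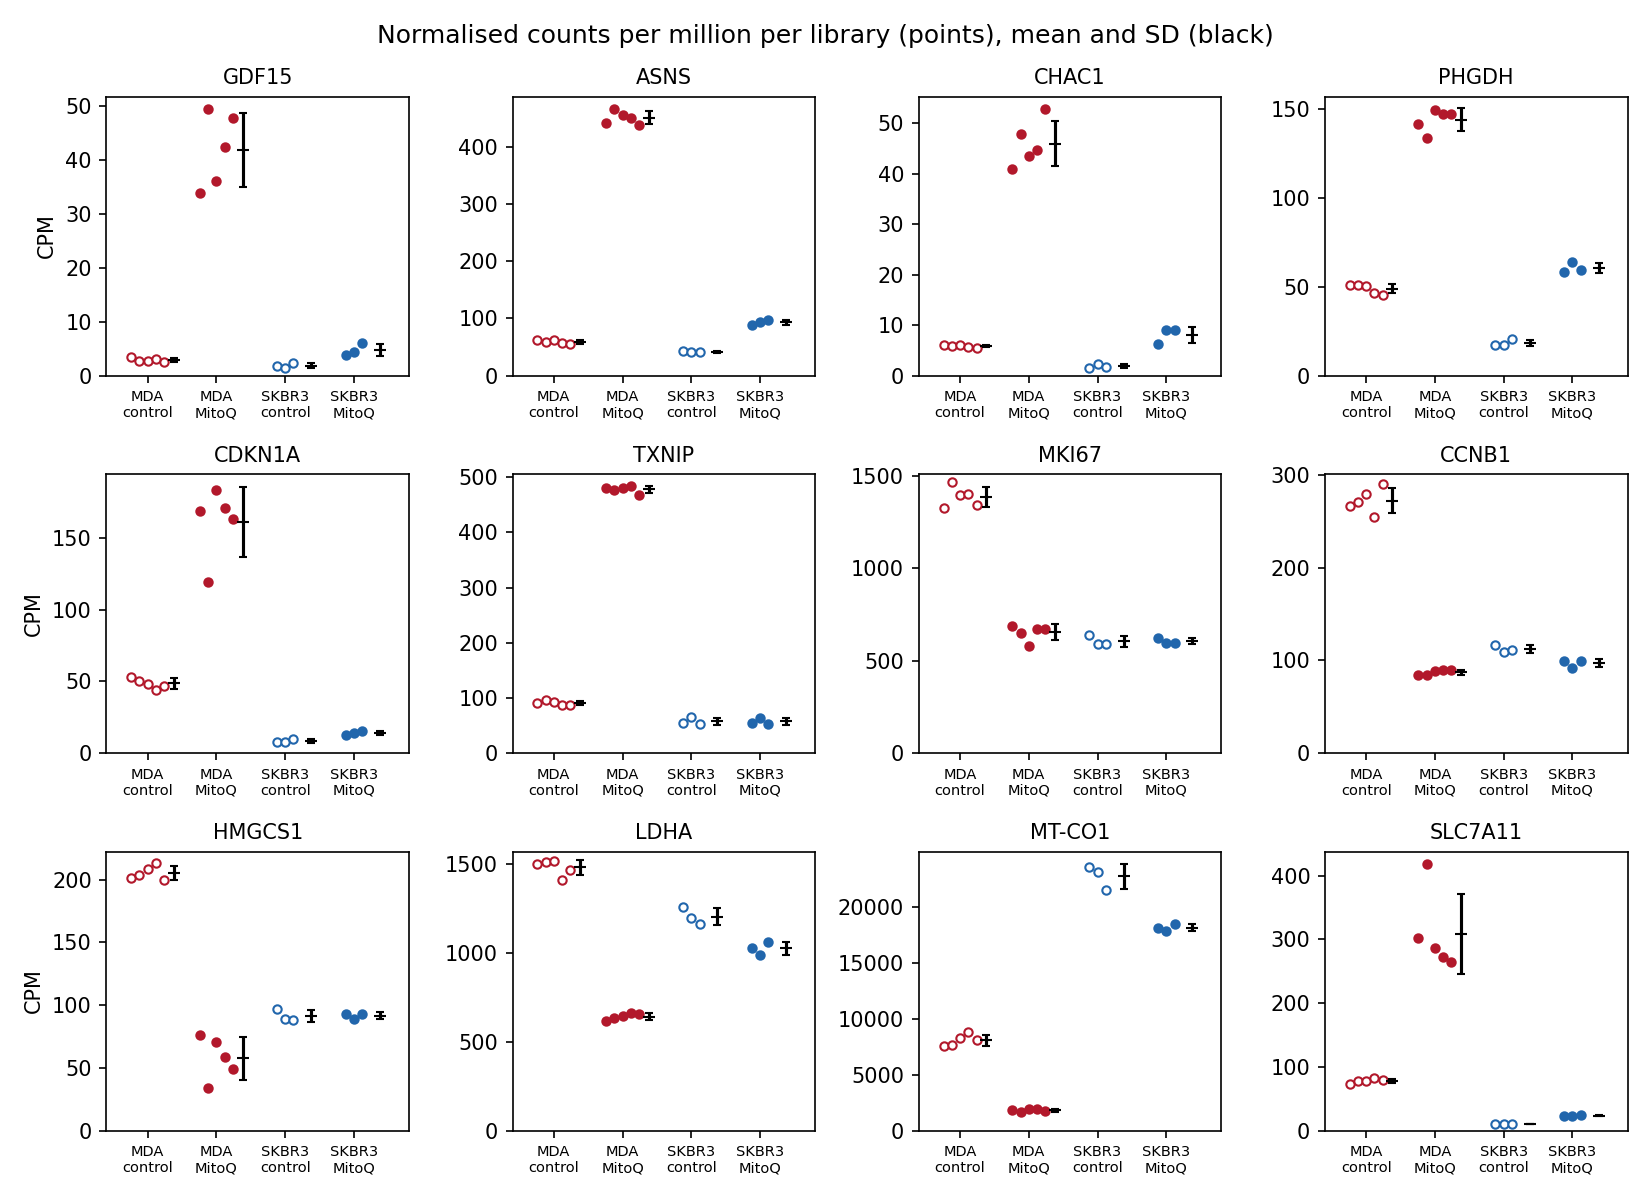
Normalised CPM (vertical axis, from 0) of 12 genes in each library (points; open, control; filled, MitoQ) with the mean and SD of each group (black), for MDA-MB-231 (n = 5 and 5) and SKBR3 (n = 3 and 3). ASNS rises from 58.7 to 451 CPM in MDA-MB-231 and from 41.8 to 93.6 CPM in SKBR3, and TXNIP rises in MDA-MB-231 from 90.8 to 478 CPM.

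The second comparison asked the same of SKBR3. The changes there were smaller, and the genes with the largest rises included CBS and PHGDH, enzymes of cysteine and serine synthesis. CBS (ENSG00000160200, chromosome 21, 43053191 to 43076943), cystathionine beta-synthase, went from 2.32 ± 0.449 to 12.9 ± 1.62 CPM, a log2 fold change of 2.47 ± 0.15 (adjusted p = 1.82e-07). PHGDH (ENSG00000092621, chromosome 1, 119648411 to 119744226) went from 18.2 ± 1.83 to 60.4 ± 2.90 CPM, a 3.29-fold rise (adjusted p = 4.51e-09). The cystine transporter gene SLC7A11 rose 2.34-fold and ALDH1L2, a mitochondrial folate enzyme, 2.53-fold. Of 15026 genes tested 4202 changed, 2076 higher and 2126 lower, with a change of at least 2-fold in 121 of the higher and 16 of the lower genes. In a principal component analysis SKBR3 control 3 (-7.24 on the first component) lay nearer the MitoQ libraries (15.89 to 21.22) than the other controls did (-24.65 and -23.63); without it 4547 genes were called.

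The other genes among the 10 largest rises in SKBR3 were CBSL, PSG4 (3.67-fold), ADM2 (2.83-fold), MEGF6 (2.65-fold), HELZ2 (2.48-fold) and JAG2, a Notch ligand (2.32-fold). CBS shares 56.3% of its 31-base stretches with other transcripts and CBSL, its near-identical copy, 93.8%, so their counts cannot be assigned to either gene with certainty. The largest falls were those of STAC2 (-0.97 ± 0.14), ETFDH, which passes electrons from fatty acid oxidation to ubiquinone (-0.89 ± 0.068), MAGEA2B (-0.84 ± 0.21), PEG10 (-0.79 ± 0.051), EID1 (-0.75 ± 0.056), TMEM107 (-0.73 ± 0.11), FAM25A (-0.72 ± 0.17), KCNMA1 (-0.69 ± 0.12), TH (-0.68 ± 0.083) and CA8 (-0.66 ± 0.13). MAGEA2B and FAM25A share 90.4% and 84.8% of their stretches with other genes. The call of MAGEA2B was lost without SKBR3 control 2 (adjusted p = 0.0599), without MitoQ 2 (adjusted p = 0.0732), without MitoQ 3 (adjusted p = 0.0759) and in a single fit over all libraries (adjusted p = 0.222).

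The integrated stress response rose in 21 of 24 tested members in SKBR3, 21 adjusted over the list alone, with a median of 0.44 (adjusted p = 0.0881 with an estimated correlation). ASNS rose 2.24-fold, CHAC1 from 1.85 ± 0.453 to 8.06 ± 1.65 CPM, GDF15 2.51-fold and TRIB3 1.27-fold. ATF4 (0.12 ± 0.036, adjusted p = 0.0279) and DDIT3 (0.42 ± 0.15, adjusted p = 0.0463) passed narrowly. The call of ATF4 was lost without SKBR3 control 1 (adjusted p = 0.0602), control 2 (adjusted p = 0.0545), MitoQ 2 (adjusted p = 0.0689) or MitoQ 3 (adjusted p = 0.113), and in a single fit over all libraries (adjusted p = 0.157). That of DDIT3 was lost without SKBR3 control 1 (adjusted p = 0.0911), control 2 (adjusted p = 0.0576), control 3 (adjusted p = 0.119), MitoQ 2 (adjusted p = 0.194) or MitoQ 3 (adjusted p = 0.137), with DESeq2 (adjusted p = 0.0894) and in a single fit over all libraries (adjusted p = 0.0519). The serine and one-carbon list rose in 8 of 14, with 8 higher and 3 lower adjusted over the list alone (PSAT1, 1.87-fold up; adjusted p = 0.0696 with an estimated correlation). NRF2 targets rose in 10 of 21 and fell in 1, 10 and 1 adjusted over the list alone (adjusted p = 0.129 with an estimated correlation), with FTH1 1.66-fold, HMOX1 1.61-fold, NQO1 1.42-fold and TXNRD1 1.40-fold higher.

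Respiratory genes of the nucleus fell slightly in SKBR3. In complexes II to V 22 of 39 fell, 22 adjusted over the list alone, with a median of -0.21 (CYCS, cytochrome c, -0.40 ± 0.047; UQCRH, -0.41 ± 0.051), and in complex I 19 of 37 fell, 21 adjusted over the list alone (NDUFB9, -0.45 ± 0.047; NDUFA5, -0.43 ± 0.042). These lists were lost with an estimated correlation (adjusted p = 0.294 and adjusted p = 0.288). The mitochondrial ribosome fell in 38 of 73 and rose in 1, 41 and 1 adjusted over the list alone (MRPL42, -0.34 ± 0.040; adjusted p = 0.197 with an estimated correlation). The TCA cycle fell in 14 of 21 and rose in 1, 14 and 1 adjusted over the list alone (DLD, -0.37 ± 0.034; adjusted p = 0.197 with an estimated correlation). Fatty acid oxidation fell in 13 of 20 and rose in 3, 14 and 5 adjusted over the list alone (HADHB, -0.49 ± 0.044; CPT1A, -0.39 ± 0.035; adjusted p = 0.113 with an estimated correlation). Of the mitochondrially encoded mRNAs 4 of 13 fell, 4 adjusted over the list alone, with a median of -0.39 (MT-ND5, -0.56 ± 0.087; MT-CO1, -0.32 ± 0.047; adjusted p = 0.405 with an estimated correlation), and their share of counts went from 6.46% ± 0.717 to 5.19% ± 0.0590. Antioxidant enzymes fell in 9 of 21 and rose in 1, 11 and 1 adjusted over the list alone (PRDX3, -0.43 ± 0.041; CAT, -0.47 ± 0.055; adjusted p = 0.288 with an estimated correlation). MYC targets fell in 16 of 26 and rose in 2, 17 and 3 adjusted over the list alone (UTP20, -0.28 ± 0.037; adjusted p = 0.148 with an estimated correlation). The endoplasmic reticulum response fell in 10 of 20, 11 adjusted over the list alone (HSP90B1, -0.31 ± 0.037; adjusted p = 0.288 with an estimated correlation).

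Adhesion and inflammatory genes rose in SKBR3. In the matrix list 17 of 28 rose, 21 adjusted over the list alone (ITGB4, 1.72-fold; ITGA3, 1.53-fold; TIMP2, 1.46-fold; adjusted p = 0.0783 with an estimated correlation). NF-kappaB targets rose in 10 of 15, 10 adjusted over the list alone (NFKBIA, 1.39-fold; adjusted p = 0.0783 with an estimated correlation). Basal B markers rose in 9 of 16, 10 adjusted over the list alone (CD44, 2.18-fold; adjusted p = 0.0783 with an estimated correlation). Mesenchymal markers rose in 6 of 13 and fell in 1, 6 and 1 adjusted over the list alone (adjusted p = 0.143 with an estimated correlation). The TGF-beta response rose in 10 of 20 and fell in 3, 12 and 3 adjusted over the list alone (adjusted p = 0.197 with an estimated correlation). Immediate early genes rose in 10 of 18, 11 adjusted over the list alone (JUN, 1.68-fold; adjusted p = 0.197 with an estimated correlation). Stem cell markers rose in 6 of 16 and fell in 1, 7 and 1 adjusted over the list alone (NOTCH3, 1.57-fold; adjusted p = 0.197 with an estimated correlation). Interferon genes rose in 8 of 26 and fell in 1, 8 and 1 adjusted over the list alone (OAS3, 1.64-fold; adjusted p = 0.288 with an estimated correlation). Epithelial markers rose in 8 of 20, 9 adjusted over the list alone (KRT7, 1.35-fold; adjusted p = 0.381 with an estimated correlation). The signalling list of AMPK, mTOR and insulin rose in 6 of 22 and fell in 2, 7 and 3 adjusted over the list alone (IGF1R, 1.49-fold; adjusted p = 0.329 with an estimated correlation). SRC and focal adhesion kinases rose in 6 of 14 and fell in 1, 8 and 1 adjusted over the list alone (SRC, 1.33-fold; adjusted p = 0.381 with an estimated correlation); this list was lost without SKBR3 MitoQ 3 (adjusted p = 0.0836).

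Of the leukocyte markers, kept as a check for other cells, 3 of the 5 tested rose in SKBR3, 3 adjusted over the list alone (adjusted p = 0.197 with an estimated correlation). They were CSF1R, from 38.7 ± 2.15 to 68.3 ± 4.37 CPM, CD68, from 5.72 ± 0.322 to 8.64 ± 0.941 CPM with 77.3% of its stretches in other transcripts, and ITGAM, from 0.320 ± 0.114 to 0.987 ± 0.410 CPM, a call lost without SKBR3 MitoQ 2 (adjusted p = 0.0970). The histone list rose in 4 of 13, 4 adjusted over the list alone (H1F0, log2 0.32 ± 0.042; HIST1H2BC, 1.29-fold; HIST1H2BD, 1.18-fold; adjusted p = 0.381 with an estimated correlation), and cytosolic ribosomal protein genes rose in 25 of 62, 28 adjusted over the list alone (RPL13, 1.36-fold; adjusted p = 0.410 with an estimated correlation). Mitosis (median -0.033) and cholesterol synthesis (median -0.0010) did not pass the list test. MKI67 (605 ± 28.6 and 605 ± 15.8 CPM), HMGCS1 (91.6 ± 4.87 and 91.7 ± 2.45 CPM), TXNIP (57.8 ± 6.28 and 57.3 ± 6.06 CPM) and ERBB2 (5351 ± 424 and 5666 ± 131 CPM) did not pass the gene test, except ERBB2 without SKBR3 control 3 (adjusted p = 0.00899). CDKN1A rose 1.65-fold, and TFAM (-0.25 ± 0.040), HK2 (-0.30 ± 0.037) and LDHA (-0.23 ± 0.042) fell. SOD2 (-0.16 ± 0.050, adjusted p = 0.0293) was lost without SKBR3 control 1 (adjusted p = 0.104), control 2 (adjusted p = 0.143), MitoQ 2 (adjusted p = 0.133) or MitoQ 3 (adjusted p = 0.125), with plain library totals (adjusted p = 0.0563) and in a single fit over all libraries (adjusted p = 0.180). PPARGC1A and VIM had too few counts in SKBR3 to be tested.

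In SKBR3 26 of 42 lists passed the test, 17 up and 9 down, and 0 with camera's estimated correlation, where 10 lists had an unadjusted p under 0.05 and fry called 32. By fry the mitochondrially encoded mRNAs (adjusted p = 0.0698) and the cytosolic ribosomal proteins (adjusted p = 0.0659) did not pass. The median and the test differed in sign for cholesterol synthesis, fibroblast markers and luminal markers, and the mean for heat shock. The remaining lists that did not pass had medians of 0.046 (E2F), -0.12 (coenzyme Q synthesis), -0.082 (glycolysis), 0.19 (p53 targets), -0.12 (mitochondrial DNA maintenance), -0.071 (fusion and fission), -0.058 (mitochondrial chaperones), 0 (fatty acid synthesis), 0.038 (lysosome and autophagy), -0.074 (hypoxia), -0.090 (heat shock), 0.075 (apoptosis), -0.065 (fibroblast and endothelial markers) and 0.015 (luminal markers). The count of called genes was 2565 without SKBR3 MitoQ 2, 2788 in a single fit over all 16 libraries (61.7% of them higher against 49.4%) and 472 in the test against a change of 1.2-fold. On simulated data with as many libraries but only 200 changed genes, 11.5% of the calls were false. That share depends on how many genes change, so it does not carry over to the calls here. The 10 splits of the 6 libraries are too few to exclude chance for the list count (26, and at most 23 in another split). For 22 of the 26 called lists no other split had a median as large. Every other split mixes treated and control libraries, so a smaller median was likely in advance.

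The third comparison asked whether the response to MitoQ differed between the lines, by the interaction of line and treatment over all 16 libraries. The integrated stress response rose more in MDA-MB-231, and the mitosis and histone lists fell there. In SKBR3 the mitosis list did not pass the list test, with a median of -0.033, and the histone list had a median of 0.142. The effect in SKBR3 minus that in MDA-MB-231 had a median of 1.03 for mitosis genes, where 30 of 30 members differed, 30 adjusted over the list alone. It was -1.16 for the integrated stress response, with 22 of 26 members different, 22 adjusted over the list alone, and 1.33 for the histone list, with 12 of 13, 12 adjusted over the list alone. These lists held with an estimated correlation (adjusted p = 1.24e-05, adjusted p = 0.00415 and adjusted p = 0.0139). Single genes with a large difference were CTH (-3.10 ± 0.12), TXNIP (-2.35 ± 0.084), KIF20A (2.07 ± 0.073), AURKA (1.68 ± 0.056) and ASNS (-1.73 ± 0.073).

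Cholesterol synthesis differed in 22 of 25 members, 22 adjusted over the list alone, with a median of 1.32 (ACAT2, 1.37 ± 0.079; adjusted p = 0.125 with an estimated correlation). The mitochondrially encoded mRNAs differed in 10 of 13, 11 adjusted over the list alone, with a median of 1.29 (MT-CO1, 1.87 ± 0.090; MT-CO3, 2.61 ± 0.14; adjusted p = 0.0925 with an estimated correlation). Glycolysis had a higher effect in SKBR3 in 16 of 24 and a lower in 1, 17 and 1 adjusted over the list alone (LDHA, 1.02 ± 0.063; PDK1, 1.18 ± 0.10; adjusted p = 0.322 with an estimated correlation). The heat shock list had a higher effect in SKBR3 in 9 of 11, 9 adjusted over the list alone (HSPA8, 0.77 ± 0.066; adjusted p = 0.0574 with an estimated correlation). Cytosolic ribosomal proteins had a higher effect in 45 of 62, 51 adjusted over the list alone, with a median of 0.36 (RPS7, 0.72 ± 0.091; adjusted p = 0.643 with an estimated correlation). The hypoxia list differed in 14 of its 20 members, higher in 10 and lower in 4, 10 and 4 adjusted over the list alone (PDK1, 1.18 ± 0.10; adjusted p = 0.0574 with an estimated correlation).

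The other lists past the test were lost with an estimated correlation. For each, the median, that adjusted p, and the numbers of members with a higher and a lower effect in SKBR3 are given, the latter also adjusted over the list alone. Higher in SKBR3 were E2F (0.22, adjusted p = 0.534, 17 and 0, 19 and 0 adjusted over the list alone), complexes II to V (0.22, adjusted p = 0.71, 22 and 0, 24 and 1) and fatty acid synthesis (0.42, adjusted p = 0.493, 10 and 2, 10 and 2). Lower in SKBR3 were the TGF-beta response (-0.49, adjusted p = 0.125, 2 and 11, 3 and 11), p53 targets (-0.38, adjusted p = 0.0574, 1 and 10, 2 and 11), immediate early genes (-0.38, adjusted p = 0.322, 2 and 10, 2 and 12) and luminal markers (-0.27, adjusted p = 0.322, 0 and 9, 1 and 10). So were the serine list (-0.13, adjusted p = 0.270, 4 and 7, 5 and 7), the AMPK and mTOR list (-0.11, adjusted p = 0.216, 5 and 8, 5 and 9) and NRF2 targets (-0.26, adjusted p = 0.322, 2 and 10, 2 and 11). Fatty acid synthesis was also lost without MDA-MB-231 MitoQ 5 (adjusted p = 0.0511), with a stricter filter (adjusted p = 0.0517) and with plain library totals (adjusted p = 0.0622). The difference between the lines did not pass the test for PHGDH (0.20 ± 0.092, adjusted p = 0.0957), HMOX1 (0.088 ± 0.20, adjusted p = 0.801), MT-ND1 (0.38 ± 0.18, adjusted p = 0.143) or MT-ND2 (-0.0090 ± 0.18, adjusted p = 0.997).

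Of 17094 genes tested, 5823 had an effect that differed between the lines, 3269 with the higher value in SKBR3 and 2554 with the lower. With plain library totals 41.6% of the called genes had the higher value in SKBR3, against 56.1% with scaling factors, so which side held more genes depended on the scaling. Among the 13785 genes tested within both lines, 5580 differed. The rule for named genes picked 12 genes here, and 10 of them were near the floor in 1 of the lines, so that their fitted differences are not interpretable and their calls are not read here. These 10 were HIST1H1B, HIST1H3I, HIST1H1D and RAB25, near 0 in MDA-MB-231, and HIST1H2AA, GPC4, INHBE, GSTM1, GPSM3 and IFI16, near 0 in SKBR3. The other two were S100P (-4.92 ± 0.34), which went from 0.192 to 9.87 CPM in MDA-MB-231, near the floor in its controls, so that the size of the difference is not interpretable, and from 90.1 to 149 CPM in SKBR3, and SLC16A1 (-3.80 ± 0.21), which went from 1.14 to 14.5 CPM in MDA-MB-231 and from 9.29 to 8.46 CPM in SKBR3. In total 19 of 43 lists passed, 11 up and 8 down, and 3 with an estimated correlation; the splits of the libraries reshuffle treatment within the lines and do not test whether the effects are equal.

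Across the 13785 genes tested in both lines, the fold changes correlated weakly, with Pearson r = 0.218 and Spearman rho = 0.186; genes are not independent replicates. Of the 2701 genes called in both lines 67.4% changed in the same direction. There were 869 genes higher in both, where independent lists would share 580, and 952 lower in both against 594. In opposite directions there were 391 genes higher in MDA-MB-231 and lower in SKBR3, against 614, and 489 of the reverse, against 561. ASNS, CHAC1, PHGDH, GDF15 and NQO1 were among the genes higher in both lines.

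**Figure D4:**
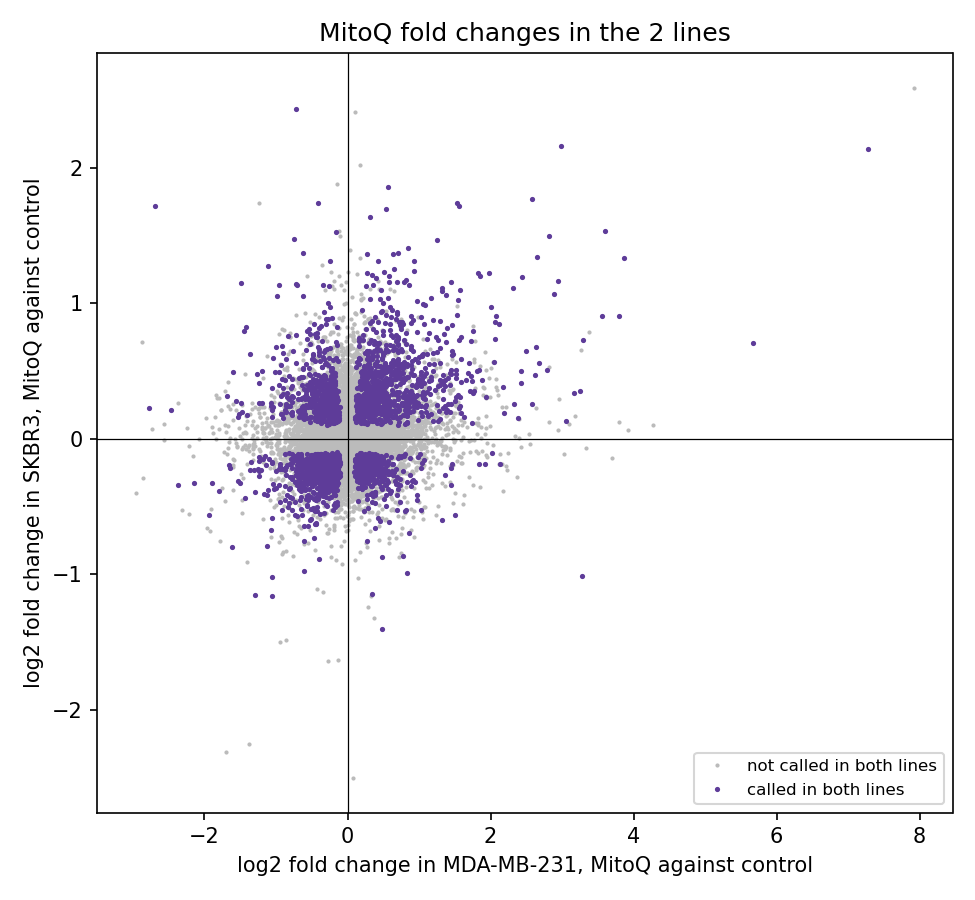
Log2 fold change of each gene tested in both lines, MDA-MB-231 (horizontal axis) against SKBR3 (vertical axis); purple points were called in both lines. Of the 2701 purple points 67.4% lie in the quadrants where both lines changed the same way.

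The last comparison set the SKBR3 controls (n = 3) against the MDA-MB-231 controls (n = 5), as background to the response. SKBR3 expressed the luminal and HER2 genes: ERBB2 was 99.5-fold higher (53 ± 3.41 CPM in MDA-MB-231 and 5282 ± 468 CPM in SKBR3), GRB7, its neighbour on the amplicon, 298-fold, AGR2 363-fold and FOXA1, a luminal transcription factor, 84.4-fold. MDA-MB-231 expressed the mesenchymal genes: VIM (vimentin) was at 3339 ± 89.0 CPM against 0.178 ± 0.0800 CPM, AXL at 1788 ± 76.6 against 0.603 ± 0.304 CPM and FOSL1 at 453 ± 19.3 against 0.858 ± 0.0935 CPM. SPARC had 14490 counts over the MDA-MB-231 controls and 1 over those of SKBR3, a ratio of 6970 with a 95% counting interval of 1250 to 275000. The luminal list was higher in SKBR3 in 19 of 21 members and lower in 1, 19 and 1 adjusted over the list alone (adjusted p = 0.0894 with an estimated correlation), and the basal B list was lower in 19 of 20 and higher in 1, 19 and 1 adjusted over the list alone (adjusted p = 0.0894 with an estimated correlation). Of the 12 of 43 lists past the test, 3 were higher and 9 lower in SKBR3, and 0 held with camera's estimated correlation, where 8 had an unadjusted p under 0.05 and fry called 37. The others were the matrix list (median -4.19, adjusted p = 0.0894 with an estimated correlation), mesenchymal markers (-5.45, adjusted p = 0.0894), epithelial markers (3.73, adjusted p = 0.107), mitosis (-1.25, adjusted p = 0.115), metallothioneins (-4.51, adjusted p = 0.115), immediate early genes (-0.68, adjusted p = 0.238), SRC kinases (-0.66, adjusted p = 0.411), the TCA cycle (0.56, adjusted p = 0.531), histones (-1.45, adjusted p = 0.607) and cholesterol synthesis (-0.60, adjusted p = 0.607). In all, 14177 of 16398 genes differed, 6889 higher and 7288 lower in SKBR3. The lines also differed in passage, so the difference is one of these cultures, and the 2 factors cannot be separated.

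The 2 lines also differed along the histone cluster of chromosome 6, a feature chosen after its values were seen. Levels here are CPM of plain library totals, as means over the 10 MDA-MB-231 libraries, control and MitoQ, and over the 3 SKBR3 controls. Of the 45 genes of the cluster at 10 CPM or more in either line, 15 were under 0.5 CPM in MDA-MB-231. They formed 2 runs, unbroken among these 45 genes. The first held 12 genes from HIST1H2AD to HIST1H2BI (chromosome 6, 26198851 to 26273356), at 0 to 0.335 CPM in MDA-MB-231 and 65.3 to 340.4 CPM in SKBR3. The second held 3 genes from HIST1H2AL to HIST1H3I (27865355 to 27872315), at 0.0244 to 0.0617 CPM in MDA-MB-231 and 47.1 to 338.9 CPM in SKBR3. The opposite held for 2 neighbours at the start of the cluster, HIST1H2AA and HIST1H2BA, at 10.5 and 50.4 CPM in MDA-MB-231 and 0.0479 and 0.439 CPM in SKBR3.

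**Figure D5:**
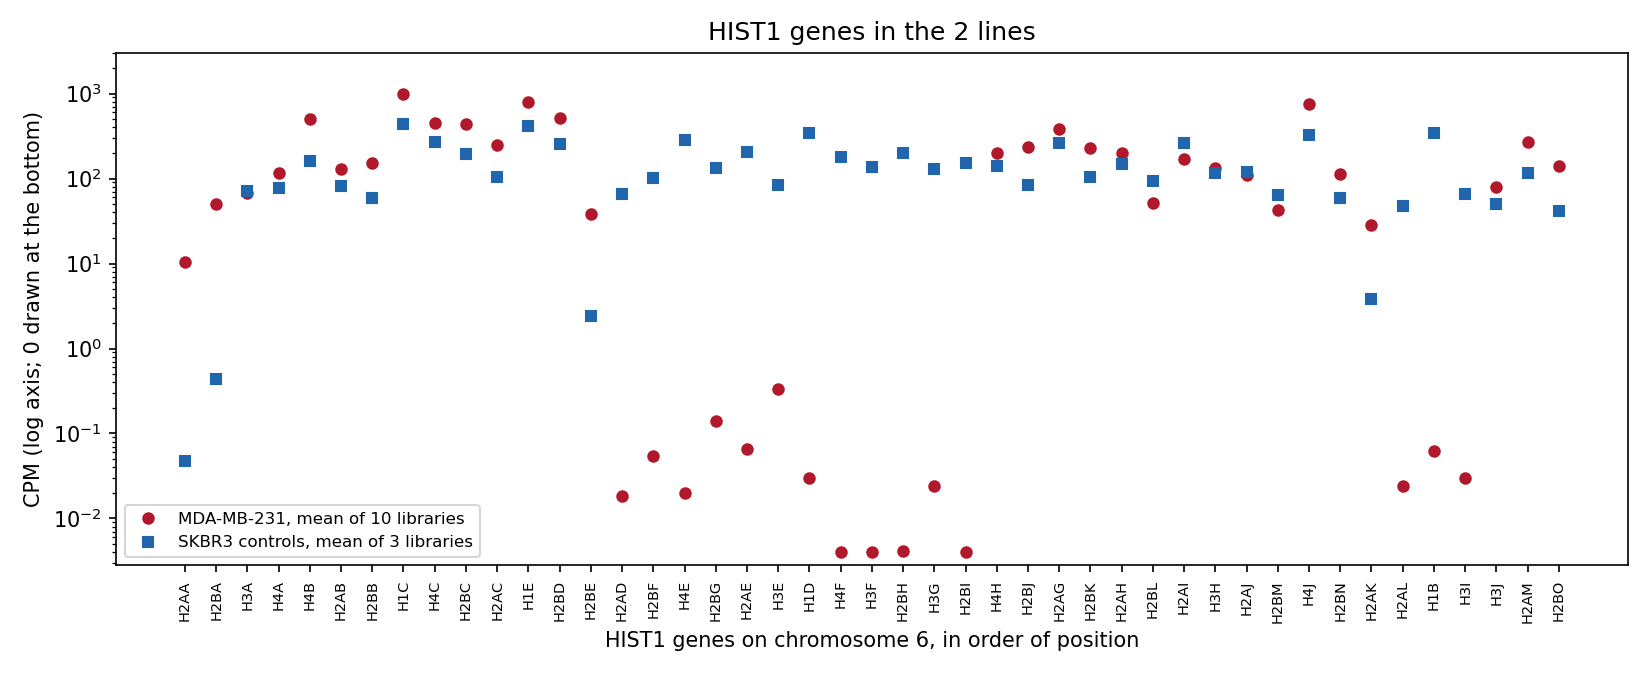
CPM of histone genes in order of position along chromosome 6 (vertical axis, log scale, values of 0 drawn at the bottom) as means over the MDA-MB-231 libraries, control and MitoQ (n = 10), and over the SKBR3 controls (n = 3). The runs of 12 and 3 neighbouring genes near 0 in MDA-MB-231 lie at 47.1 CPM or more in SKBR3.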

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

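The tests for a library far from the others and every weighing below were chosen after the results were seen, except those of nuclear copies and of scaling for the mitochondrial mRNAs. In groups of 5, a library was taken as far from the others when its gap to the nearest of them exceeded 0.71 of the group's range, which chance gives in about 1 of 20 groups. Of 278 groups of named genes and library measures in MDA-MB-231, 23 passed, where chance gives about 13.9; the number of groups was widened with the genes named. MitoQ 2 was the far library in 13 of them, and it also stood apart on the second component of a principal component analysis (-32.41). Its ratios were SLC16A1 (0.829), HELZ2 (0.844), SLC7A11 (0.75), HMOX1 (0.79), TXNRD1 (0.863), VIM (0.946), DDIT4 (0.735), DUSP1 (0.715), CS (0.794), ITGB4 (0.714), CAT (0.729), MRPL35 (0.895) and JUN (0.823). In the MitoQ group the others were KLHDC7B (0.84) and FOXA1 (0.792) for MitoQ 3, HIST1H2BM (0.751) for MitoQ 1 and CSF1R (0.736) for MitoQ 5. In the controls they were PRDX3 (0.749), IGF1R (0.857), CXCL8 (0.726) and NDUFAB1 (0.715) for control 5, EID1 (0.809) for control 1 and SEL1L3 (0.736) for control 2. Without MitoQ 2, 9169 genes were called in place of 8805.

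The effect of MitoQ differed between the lines, by the interaction test of edgeR, for 5823 genes, and for 99 of the 121 named genes tested in both. Values are the log2 effect in SKBR3 minus that in MDA-MB-231. Stress, amino acid and one-carbon genes had GDF15 (-2.51), ATF4 (-0.67), DDIT3 (-1.11), ASNS (-1.74), CHAC1 (-0.77), TRIB3 (-2.78), SESN2 (-1.78), DDIT4 (-1.02), NUPR1 (-2.52), CTH (-3.10), ADM2 (-1.28) and SLC7A11 (-0.71). For the one-carbon enzymes the values were PSAT1 (-1.13), MTHFD2 (-1.57) and ALDH1L2 (-1.27). For redox and iron genes they were NQO1 (-0.97), FTH1 (-0.49), FTL (-1.42), PRDX3 (0.27) and CAT (0.30). Genes of division had MKI67 (1.13), KIF20A (2.07), AURKA (1.68), CCNB1 (1.47), PIF1 (2.72), GINS2 (0.79) and CDKN1A (-0.98). Histone genes had HIST1H2BM (3.05), HIST1H3J (2.84), HIST1H2AB (2.61), HIST1H2BB (2.73), HIST2H3D (2.68), HIST1H4C (1.78), H1F0 (0.67), HIST1H2BC (1.47) and HIST1H2BD (1.33). Mitochondrially encoded mRNAs had MT-ND6 (2.60), MT-CO3 (2.61), MT-CO1 (1.87), MT-CYB (1.46) and MT-ND5 (1.41).

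Nuclear genes of respiration and of mitochondrial protein synthesis had ATP5MC3 (0.64), ATP5MC1 (0.92), NDUFB3 (0.49), NDUFAB1 (0.39), CS (0.32), DLD (0.27) and MRPL35 (0.41). Those of fatty acid oxidation had ETFDH (-0.45), CPT1A (-0.27) and HADHB (-0.26), and sterol and fatty acid synthesis HMGCS1 (1.88), ACAT2 (1.37), MVK (1.51), CYP51A1 (1.31) and ELOVL6 (0.70). Glycolysis, hypoxia and nutrient genes had LDHA (1.02), PDK1 (1.18), SLC16A1 (-3.80), VEGFA (-0.69), BNIP3 (1.2), TXNIP (-2.35) and IGF1R (0.75). Chaperones and translation had HSPA8 (0.77), HSPH1 (0.75), HSP90B1 (0.20), RPS7 (0.71), RPL13 (0.41) and UTP20 (0.30). Matrix, TGF-beta and marker genes had COL6A3 (-3.00), ITGA3 (-0.38), ID1 (-0.80), TIMP2 (0.44), CD44 (0.92), EGFR (-0.56), KLF4 (-0.90), KRT7 (-0.51), SRC (0.28), XBP1 (-1.41) and FOXA1 (-0.48). Inflammatory, interferon and early genes had TNFAIP3 (-0.77), NFKBIA (0.39), DDX58 (1.31), STAT2 (-0.62), OAS3 (0.32), DUSP1 (-1.0), JUN (0.62), CSF1R (1.26) and CD68 (0.89). Other genes of large change in either line had KLHDC7B (-5.10), S100P (-4.92), PIP5KL1 (-2.85), SEL1L3 (-2.00), PSG4 (2.05), MEGF6 (0.61), JAG2 (1.12), PEG10 (0.38), KCNMA1 (-1.50) and CA8 (-1.001). KLHDC7B and S100P were near the floor in the MDA-MB-231 controls, so the size of their differences is not interpretable.

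Of the lists, 19 differed between the lines by camera, and 3 of them with an estimated correlation between genes: mitosis, the integrated stress response and histones. The median difference was above 0 for G2/M and mitosis (1.03), replication-dependent histones (1.33), cholesterol synthesis (1.32), mitochondrially encoded mRNAs (1.29), cytosolic ribosomal proteins (0.36) and cytosolic heat shock response (0.50). It was also above 0 for glycolysis and lactate (0.42), E2F and DNA replication (0.22), nuclear OXPHOS complexes II to V (0.22), hypoxia response (0.45) and fatty acid synthesis and desaturation (0.42). It was below 0 for integrated stress response (-1.16), TGF-beta response (-0.49), p53 targets (-0.38) and immediate early genes (-0.38), and for HER2 amplicon and luminal markers (-0.27), serine and one-carbon metabolism (-0.13), AMPK, mTOR and insulin signalling (-0.11) and NRF2 targets (-0.27).

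The mitochondrially encoded mRNAs fell in MDA-MB-231, with a median of -1.78. Reads moving to nuclear copies of these genes were argued against by the summed CPM of genes and copies, which had a log2 fold of -1.62 ± 0.21. For summed CPM the value after ± is the SD of differences between single libraries, not an SE. The scaling factors as the cause were argued against by a median of -1.725 with plain library totals. Leaving the factors out moved the median of all genes by only 0.06, so the fall does not come from them. Both scalings give relative levels, and a change in the total RNA of the cells was not tested. A single common fall of every mRNA was argued against by the SD of the members' log2 fold changes, 0.817, beside a median SE of 0.101. MitoQ may lower these mRNAs unequally in this line, a hypothesis found and tested on the same data, and whether DNA copy number, transcription or decay changed was not tested.

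Genes of mitosis and histone genes fell in MDA-MB-231. Reads moving between histone copies were argued against by the summed CPM of the HIST1 and HIST2 genes, with a log2 fold of -1.25 ± 0.14 (SD of differences between single libraries). Fewer cells in S phase as the whole cause was weighed by the E2F list, whose median of -0.107 (SD 0.192) lay nearer 0 than that of the histone list. This weighing takes it that fewer such cells would lower both lists equally. That was not tested, so the weighing does not decide. For the histone genes a lower yield of RNA without a poly(A) tail cannot be told apart from a change in expression, since 0 rows of other such RNAs were in the table. A change in the cell cycle under MitoQ could also give such falls and was not tested.

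In MDA-MB-231, over its 10 control and MitoQ libraries, runs of neighbouring histone genes lay near 0. The same genes had a median of 137 CPM in the SKBR3 controls. They were picked at 10 CPM or more in either line and under 0.5 CPM in MDA-MB-231, so a level above 10 CPM in SKBR3 was fixed by the choice. That level therefore does not decide whether reads were given to other histone copies in the counting. The share of sequence found in annotated transcripts of other genes was 0.0% for HIST1H1D, 1.8% for HIST1H1B and 3.9% for HIST1H3I. Their highest counts in any MDA-MB-231 library were 3, 5 and 5. For these named genes the low shares argued against reads given to other copies. For the other genes of the runs this was not decided. A chance scatter of genes near 0 was weighed by a scan over all autosomes. It took the 10262 protein-coding genes at 10 CPM or more in the controls of either line. The share of random orders with as many runs of 3 or more neighbours near 0 was 0.001, the smallest that 1000 orders can give. The histone runs were seen first and made up 2 of the 3 runs counted, so the scan gives no independent support. Random orders also treat neighbouring genes as unrelated. A loss of these stretches of DNA or their silencing could each give such runs, and neither was tested. The lines also differed in passage.

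Other splits of the same libraries were tested for each count. In MDA-MB-231, 1 of 100 splits, the real one, gave as many genes (8805, highest other 0). If the libraries are independent, this argued against a chance assignment to the groups. For lists 5 of 100 did (27, highest other 28), and chance was not excluded. The split with 28 lists differed from the real one by 2 libraries. It kept part of the treatment contrast, so its count does not stand for chance alone. In SKBR3, the 10 splits, with 1 the real one, were too few for a share under 0.05, for genes (4202, highest other 3) and for lists (26, highest other 23). Between control lines 1 of 56 splits gave as many genes (14177, highest other 0), which argued against a chance assignment in the same way. The origin of the replicates was not given, so a culture or batch shared within a group cannot be told apart from treatment or line. For the difference between the lines 1 of 100 gave as many genes (5823, highest other 5069) and 28 of 100 as many lists (19, highest other 30). For 5 of these 19 called lists no other split drawn had a median as large. These splits reshuffle treatment within the lines, so they stand for no effect in either line and not for equal effects, and they say nothing on chance for a difference.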

How the results depend on the processing

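Plain library totals, the thinned libraries, the interaction among genes tested within both lines and, for the lists, mitochondrial genes left out were chosen after seeing the data; the other alternatives were planned. No called gene or list named in the text reversed its direction. Which side held more of the called genes did change: for the difference between the lines with plain library totals, in MDA-MB-231 in a single fit over all libraries (4551 higher and 4688 lower), and in SKBR3, where the sides were near equal, under several alternatives. Tested against a 1.2-fold change, a stricter question by construction, 4400 genes passed in MDA-MB-231, 472 in SKBR3 and 2877 for the difference between the lines. In SKBR3 the count was 2436 at an adjusted p under 0.01 and 2788 in a single fit over all libraries, which shares 1 estimate of the spread between the lines. With an estimated correlation 11 lists passed in MDA-MB-231, 0 in SKBR3 and 3 for the difference. The correlation between the lines was 0.25 among genes with a mean of at least 10 CPM in both, and the cause was not tested.

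Leaving out each library in turn gave 8296 to 9169 genes in MDA-MB-231, 2565 to 4547 in SKBR3, 5073 to 6212 for the difference and 13873 to 14093 between control lines. The lowest value in SKBR3, 2565, came without MitoQ 2; the cause was not tested. The lists numbered 27 to 29, 26 to 27 and 18 to 20, and the correlation was 0.187 to 0.233. Same-numbered libraries did not deviate together in MDA-MB-231 (r from -0.277 to 0.064), and in SKBR3 2 of 3 pairs were over 0.1 (r from 0.053 to 0.185), where each control was closest to its own number, as a hint from the data. With a replicate block, 8363, 4758, 5416 and 13916 genes passed in the same order, with 27, 26 and 19 lists and a correlation of 0.217.

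With plain library totals the gene counts were 8821, 4084, 5904 and 14162, and 28, 26 and 18 lists passed. The median of all genes moved by 0.06 in MDA-MB-231 and by -0.091 for the difference. MDA-MB-231 thinned to 3 and 3 libraries of the SKBR3 totals gave a median of 7148 genes over 10 draws (6332 to 8495). Among genes tested within both lines, 5580 of 13785 differed. Of 362 results for a named gene or list in a comparison, 107 ended or gained a call under at least 1 alternative, 49 for genes and 58 for lists. Counted once per alternative there were 189 such changes: 43 in the test against a 1.2-fold change, 58 with an estimated correlation, 54 without 1 library and 34 elsewhere.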

Other observations

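The scans described here were chosen after the data were seen. Histone genes outside the fixed list moved with it. Of 37 such HIST1 and HIST2 genes tested in MDA-MB-231, 36 fell and 0 rose by edgeR, with log2 fold changes from -3.58 to -0.24 and a median of -1.52. In SKBR3 15 of 52 rose and 1 fell, with a median of 0.12. The summed level of all 83 HIST1 and HIST2 genes in the table, in the list or not, went from 16690 ± 888 to 7030 ± 569 CPM in MDA-MB-231. In SKBR3 it went from 9729 ± 491 to 10840 ± 565 CPM, a log2 fold of 0.16 ± 0.10 (SD of differences between single libraries, not an SE).

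A scan took in genome order the 10262 protein-coding autosomal genes at 10 CPM or more in the controls of either line. It looked for runs of at least 3 neighbours under 0.5 CPM over the libraries of 1 line and at 10 CPM or more in the controls of the other. Neighbours are adjacent among the scanned genes only, and genes left out can lie between them. The random orders treat neighbouring genes as unrelated. MDA-MB-231 had 3 such runs, where 1000 random orders gave at most 1 and a median of 0. They were the 2 histone runs, the first with 1 more neighbour, and IVL, S100A9 and S100A8, genes of the epidermal cluster of chromosome 1, at 34.3 to 231 CPM in the SKBR3 controls. SKBR3 had 2 runs, where random orders gave a median of 0 and at most 2, with a share of 0.009 that gave as many: ROR1, CACHD1 and RAVER2 on chromosome 1 (13.2 to 72.7 CPM in the MDA-MB-231 controls), and the forkhead genes FOXQ1, FOXF2 and FOXC1 on chromosome 6 (14.3 to 19.2 CPM in those controls).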
